A study of Caenorhabditis elegans with 6 samples.

How the data were processed

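Poly(A) RNA of whole-worm pools was sequenced from 6 stranded libraries made with a KAPA kit, 3 per treatment, per the labels' protocols. The labels give each library a batch (2, 3 or 4) with 1 library of each treatment. The submitters' processing notes name cutadapt 2.10, TopHat2 2.1.1, HTSeq 2.01, DESeq2 1.36.0 and the genome build WBcel235, without their settings or order. Whether HTSeq used the strand and how it treated reads shared between genes is not given in the sources used here.

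The authors' deposited table holds, for each library, counts per gene, counts divided by a size factor and a batch-corrected form of the latter. The deposited counts are whole numbers for 22416 of the 46934 rows. The other 24518 rows, of small and structural RNA types, hold no value and entered no test. The normalized signal the authors deposited equals the count over 1 constant per library, with a largest relative spread of 1.96e-14, and is given for the 18533 genes with a total count of 10 or more. The batch-corrected values, the authors' deposited values of another kind, go below 0 in 43 cases and served only for the check in the closing section and for an alternative fit.

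Groups came from the sample titles. Genes were compared between treatments with edgeR 4.0.16 in R 4.3.3 on the deposited counts: filterByExpr with a minimum count of 10 left 15519 genes, TMM factors scaled the libraries, and the quasi-likelihood test (glmQLFit, glmQLFTest) was run with the batch as a block, which leaves 2 residual degrees of freedom. The prior degrees of freedom of that fit were 3.16. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Standard errors are the log2 fold change over the square root of the F statistic, and intervals are at 95%. CPM are counts scaled to the size of the library, here after TMM. Gene lists were compared with all other tested genes by camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 and with an estimated one. With an estimated correlation, camera also refers its statistic to the 2 residual degrees of freedom, so few lists could pass. fry tested each list against no change, without reference to other genes. Lists needed 5 tested members. Families of genes sharing a name prefix, with 10 or more tested members, were tested alike. The 41 lists, the fits, the rule for named genes and the alternatives were set before the data were examined. By that rule the text names gtr-1, unc-54, rol-6 and 10 stress and longevity genes always, the genes with the highest and lowest changes among those past the threshold that moved the same way in every pair (10 each way with a letter-and-number name and 3 each way of other genes), and up to 4 members with the smallest p of each list described. Coordinates are from the Ensembl annotation of WBcel235, release 115, in which 22406 of the counted genes were found.

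The pairing comes from the batch labels. Deviations from the group mean of libraries of the same batch were correlated across genes at r = 0.71, 0.47 and 0.66 in batches 2, 3 and 4, and those of libraries of different batches at -0.71 to 0.52. The highest of the latter, the batch 3 empty vector library with the batch 4 library labelled gtr-1 RNAi, lay above the batch 3 pair, so the values do not support the pairing of batch 3 by themselves. Genes are not independent replicates. No library was a copy of another: counts of libraries within a group differed by a chi-square of 27.7 to 159 per degree of freedom. The precision of a gene's count depends on depth, and counts such as the 11 to 38 of gtr-1 carry a wide counting error.

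The tests were tried on simulated counts with 200 genes changed, drawn from the fitted means and dispersions of these libraries (15279 genes run). edgeR recovered 46.3% of genes changed 1.5-fold, 74.6% at 2-fold and 98.5% at 4-fold, and it called 34 of 15079 unchanged genes, 18.9% of its calls and thus above the nominal 5%. DESeq2 1.42.0 recovered 50.7%, 73.1% and 93.9% and called 45 unchanged genes. In 4 draws with no gene changed, edgeR called 0 to 7 genes and DESeq2 20 to 27. In a further simulation with 1 list changed 1.3-fold, camera found it with the preset correlation (adjusted p = 2.6e-20) and not with an estimated one (0.35). It called 0 of 40 other lists either way. The simulated genes were drawn independently, whereas the estimated correlation in these libraries was 0.34 for cuticle collagens and 0.66 for sperm genes. The simulation therefore cannot show how often the preset correlation calls unchanged lists of correlated genes.

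The alternatives were no batch block, no filter and a minimum count of 50, DESeq2 size factors, the DESeq2 Wald test, adjusted p under 0.1, a fold change of 2 or more as well, an estimated correlation, and leaving out each batch pair and each library. Robust quasi-likelihood and limma on the batch-corrected values were added after seeing the data. That limma fit held the treatment only, so it counted 4 residual degrees of freedom where the correction leaves 2. With the batch as a block, the partner of a left-out library no longer informs the difference between treatments. Leaving out a library therefore repeats leaving out its pair, apart from filtering, scaling and the variance shared between genes, and is not a separate check. Alternatives set for the case of normalized values were not run, because the table holds counts.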

Results

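RNA was sequenced from pools of whole Caenorhabditis elegans of strain CL2006, which expresses a human amyloid beta peptide from a body wall muscle promoter (unc-54) together with the marker plasmid pRF4, which carries rol-6. Worms were fed, over 2 generations, HT115 bacteria carrying an empty vector or bacteria making double-stranded RNA against the 3' untranslated region of gtr-1, a neuronal G protein-coupled receptor. They were collected on day 6 of adulthood at 20 °C. Each treatment was represented by 3 libraries, 1 in each of batches 2, 3 and 4, and the total count per library ran from 43067539 to 59812227. Nothing in the labels says how far the batches were separate beyond the mention of 3 sets of worms, so the p-values measure the spread between these 3 pairs.

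The first comparison was the level of the RNAi target itself. No reduction of gtr-1 (WBGene00017779, chromosome X, 802778 to 804269 in WBcel235) was measured in the libraries labelled gtr-1 RNAi. The gtr-1 counts were 32, 16 and 12 in the empty vector libraries of batches 2, 3 and 4, and 38, 26 and 11 in the libraries labelled gtr-1 RNAi. The gtr-1 level was 0.408 ± 0.166 CPM with the empty vector and 0.461 ± 0.247 CPM in the libraries labelled gtr-1 RNAi (SD, n = 3 each). The log2 fold change of gtr-1 was 0.13 ± 0.30 (SE), with a 95% interval from -0.64 to 0.89 (edgeR adjusted p = 0.886), and it was above 0 in 2 of 3 batch pairs. The exact permutation p of the log2 level of gtr-1, two-sided, was 0.5 over pairs, where 0.25 is the smallest that 3 pairs allow, and 0.8 over groups, where 0.1 is the smallest. Because the target did not separate the groups, the treated libraries are named by their label throughout, and each direction drawn from them rests on that label.

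The genes unc-54 and rol-6, taken as linked to the transgene, did not separate the groups either. The level of the amyloid beta transcript itself was not tested. unc-54, the muscle myosin heavy chain whose promoter drives the amyloid beta minigene, had a log2 fold change of 0.14 ± 0.10 (SE, edgeR adjusted p = 0.644). rol-6, a cuticle collagen whose reads include those of the marker plasmid, had 0.17 ± 0.20 (SE, edgeR adjusted p = 0.774); its value was 0.71 in batch 2, 0.18 in batch 3 and -0.39 in batch 4.

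The second comparison asked which other genes differed between the libraries labelled gtr-1 RNAi and the empty vector libraries. Of the 14 genes that rose, 3 were the aspartyl proteases asp-5, asp-2 and asp-12, at 2.04-fold, 1.62-fold and 2.00-fold, and ctsa-4.1, a homolog of lysosomal cathepsin A, rose 2.60-fold. hrg-2, a heme-responsive gene, rose 4.17-fold, and hrg-7, which encodes a secreted aspartyl protease-like protein of heme signalling, rose 2.12-fold. cth-1, a cystathionine gamma-lyase of cysteine synthesis, rose 3.92-fold. All of these changes were in the same direction in all 3 batch pairs.

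In values, hrg-2 (WBGene00010473, chromosome V, 12409415 to 12410513) went from 5.91 ± 1.82 CPM to 24.5 ± 6.55 CPM (SD, n = 3 each), a log2 fold change of 2.06 ± 0.10 (SE, edgeR adjusted p = 0.0104). C14C6.5 (WBGene00015759, chromosome V, 536628 to 537418) went from 16.18 ± 1.73 to 66.5 ± 4.59 CPM, a log2 fold change of 2.04 ± 0.07 (SE, edgeR adjusted p = 0.00673). cth-1 (WBGene00009048, chromosome V, 16100680 to 16102750) went from 13.01 ± 3.43 to 50.8 ± 12.5 CPM, a log2 fold change of 1.97 ± 0.07 (SE, edgeR adjusted p = 0.00673). asp-5 and asp-12 are neighbours on chromosome V; asp-5 went from 501 ± 22.8 to 1024 ± 84.6 CPM, with a log2 fold change of 1.03 ± 0.05 (SE, edgeR adjusted p = 0.0104). The further genes that rose were R08E5.3 (log2 fold change 1.65 ± 0.11), timm-17B.2, a subunit of the mitochondrial inner membrane translocase (1.61 ± 0.11), F01D5.1 (1.47 ± 0.11), and ugt-47, a UDP-glucuronosyltransferase (0.95 ± 0.06). F32H5.1 (0.71 ± 0.05) and ZK1320.2 (0.69 ± 0.05) also rose and are named after their values were seen. The annotation places another protein-coding gene over asp-2, R08E5.3, ugt-47, ctsa-4.1, F32H5.1 and hrg-7, so their counts are less certain where the counting could not assign a read.

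**Figure D1:**
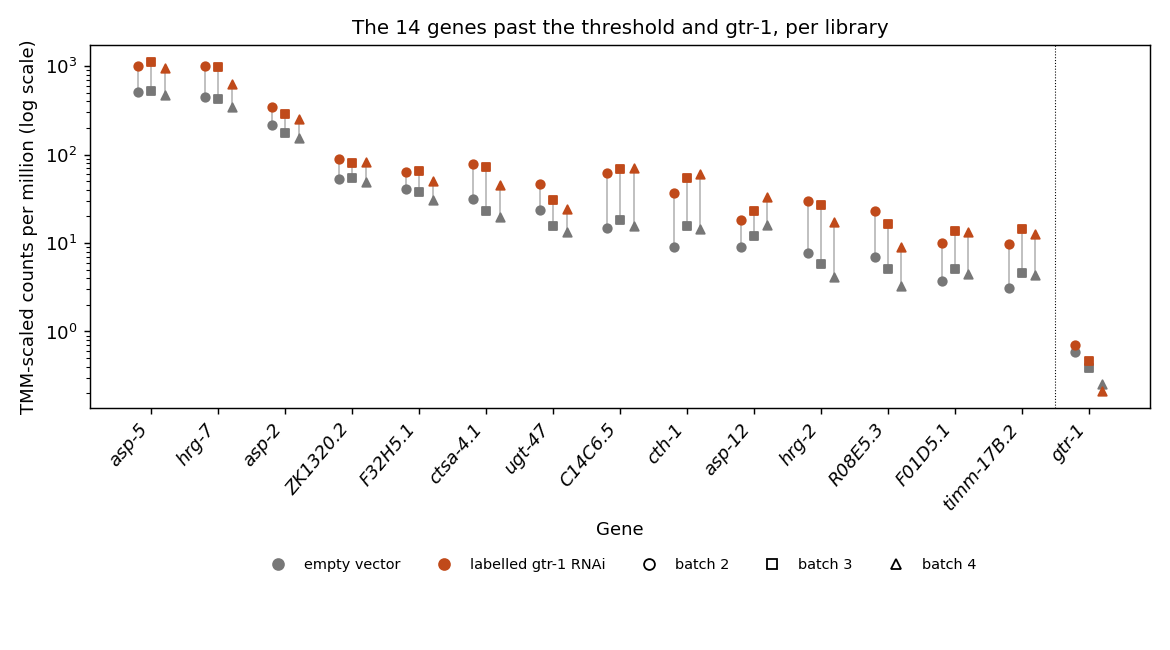
Level of each of the 14 genes that rose, and of gtr-1 on the far right, in each library, as TMM-scaled CPM on a log axis. Grey symbols are empty vector libraries, orange symbols are libraries labelled gtr-1 RNAi, the symbol shape gives the batch, and a line joins the libraries of a batch. All 14 genes were higher in the orange symbol of each batch, while gtr-1 went from 32, 16 and 12 counts to 38, 26 and 11.

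In all, 14 of the 15519 genes tested rose and 0 fell at an edgeR adjusted p under 0.05. At an unadjusted p under 0.05 edgeR gave 775 higher and 882 lower, against 776 expected by chance in all. The smallest adjusted p of a lower gene was 0.0506. DESeq2 called 244 genes higher and 96 lower, and the 14 genes were among them. edgeR with DESeq2 size factors called 132 higher and 69 lower. Without the batch as a block, 1 gene was higher and 0 were lower (231 and 157 at an unadjusted p under 0.05). Leaving out a batch pair gave 745 higher and 420 lower without batch 2, 170 and 81 without batch 3, and 0 and 0 without batch 4 (493 and 355 at an unadjusted p under 0.05); leaving out an empty vector library of batch 2, 3 or 4 gave 679 and 340, 9 and 0, or 0 and 0, and leaving out a library labelled gtr-1 RNAi gave 561 and 249, 9 and 3, or 0 and 0. At an unadjusted p under 0.05 the fits with a 0 gave 729 higher and 253 lower without the batch 3 empty vector library, and 498 and 366 or 495 and 372 without the batch 4 library of the empty vector or of the gtr-1 RNAi label. The 14 genes kept their sign in each of these fits, but their number past the threshold did not hold. As each of them was higher in all 3 batch pairs, leaving out a pair was no test of the sign. With the block, leaving out a library is not a check separate from leaving out its pair, as both rest on the same remaining pairs. Their counts differed all the same, and so did the prior degrees of freedom: 15.7 without the batch 3 pair, and 4.15 or 4.71 without its empty vector library or its library labelled gtr-1 RNAi.

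The lists of lysosomal proteases and of vacuolar ATPase subunits stood higher as groups. Both lists were taken by gene name, the proteases as cathepsins and aspartyl proteases. Where each protein acts, at lysosomes or elsewhere, was not tested for either list. The proteases asp-1 and cpr-6 are also in the list of intestine genes. Of the 23 protease genes tested, 3 rose over all genes tested. Adjusted over the list alone, 15 were higher and 2 lower. The median log2 fold change of these lysosomal proteases was 0.44, and it was 0.54, 0.44 and 0.36 in batches 2, 3 and 4. cpr-8, a cathepsin B-like protease, had a log2 fold change of 0.72 ± 0.07 (SE) but an edgeR adjusted p of 0.0745. Of 21 subunits of the vacuolar ATPase, a proton pump, none passed in edgeR over all genes tested, with 16 higher at an unadjusted p under 0.05. DESeq2 called 5 higher. Adjusted over the list alone 16 subunits were higher and 0 lower. Among them vha-6 had a log2 fold change of 0.67 ± 0.08 and vha-5 of 0.41 ± 0.05 (SE). Against all other genes, camera gave an adjusted p of 1.5e-09 for the proteases and 7.0e-08 for the ATPase with the preset correlation of 0.01. With an estimated correlation the adjusted p was 0.76 for the proteases and 0.791 for the ATPase, so both calls were made with the preset setting only. The estimate was -0.03 for the proteases, below the preset 0.01, and 0.57 for the ATPase. A higher correlation thus does not explain the lost call of the proteases, whose unadjusted p was 0.019 on 2 residual degrees of freedom. Lists of tissue genes leaned too: 13 of 14 intestine genes and 5 of 6 vitellogenins lay above 0, and 18 of 19 body wall muscle genes and 48 of 55 sperm genes below.

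Cuticle collagens, the structural proteins of the worm's exoskeleton, were higher by their median in batches 3 and 4 and not in batch 2. The median log2 fold change of the 147 tested was 0.70; it was 0.0049 in the batch 2 pair, 1.6 in batch 3 and 0.96 in batch 4, with 74, 138 and 125 of the collagens higher in the respective pair. None passed in edgeR over all genes tested (47 higher and 4 lower at an unadjusted p under 0.05), while DESeq2 called 22 higher and 2 lower; adjusted over the list alone 16 were higher and 2 lower. The collagens with the smallest p were col-103 (log2 fold change 0.44 ± 0.04), col-98 (0.45 ± 0.05), col-71 (1.35 ± 0.18) and col-138 (1.80 ± 0.25, SE); unlike the median of the list, these 4 were higher in batch 2 as well (0.46, 0.42, 1.26 and 1.28). The camera adjusted p of the list was 2.8e-19 with the preset correlation; with an estimated correlation the adjusted p was 0.76. Reads of collagens with near-identical stretches could have been split between genes by the counting.

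Immune gene groups leaned to opposite sides, the C-type lectins only slightly. The median log2 fold change was 0.21 for the antimicrobial effectors (55 higher, 26 lower) and 0.06 for the lectins (67 higher, 53 lower). That of the lectins was 0.11, 0.20 and 0.00054 in batches 2, 3 and 4. Of 31 pals genes, a family tied to the response to intracellular pathogens, none passed in edgeR over all genes tested (17 lower at an unadjusted p under 0.05) and DESeq2 called 5 lower; adjusted over the list alone 11 were lower and 0 higher. Their median log2 fold change was -0.72, and it was -0.82, -0.31 and -0.87 in batches 2, 3 and 4. pals-14 had a log2 fold change of -1.39 ± 0.16, pals-33 of -1.18 ± 0.18 and pals-38 of -1.12 ± 0.18 (SE). Of 81 antimicrobial effector genes (lysozymes, saposin-like proteins and others), 9 were higher and 2 lower adjusted over the list alone, with 0 past the threshold in edgeR over all genes (23 higher and 8 lower at an unadjusted p under 0.05) and 10 higher and 2 lower in DESeq2. Examples were the lysozyme gene lys-8 (log2 fold change 0.76 ± 0.07), the saposin-like spp-3 (0.74 ± 0.07) and irg-4 (1.73 ± 0.23, SE), each with the same sign in every pair. Of 120 C-type lectins, 8 were higher and 3 lower adjusted over the list alone, with 0 past the threshold in edgeR over all genes (25 higher and 8 lower at an unadjusted p under 0.05) and 9 higher and 3 lower in DESeq2. The lectin with the smallest p, clec-45, was at 3.74 ± 0.37, on low counts (4, 5 and 9 with the empty vector, 75, 126 and 80 in the libraries labelled gtr-1 RNAi). clec-47 was at 2.05 ± 0.25, clec-63 at 0.36 ± 0.04 and clec-61 at -1.82 ± 0.28 (log2 fold change, SE). The camera adjusted p was 3.6e-08 for the pals genes (lower), 0.00023 for the antimicrobial effectors and 0.0055 for the lectins (both higher). The adjusted p with an estimated correlation was 0.76 for all 3 lists. The calls of the effectors and the lectins ended without the batch 2 pair or either of its libraries, with adjusted p from 0.086 to 0.17 and from 0.32 to 0.38. The medians there were 0.15 to 0.22 for the effectors and 0.06 to 0.08 for the lectins. The lectin call ended also without the batch 3 empty vector library (adjusted p = 0.31). It ended too with no filter on low counts (0.28), where their median was -0.02.

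Lipid genes and genes induced by the transcription factor DAF-16, a target of the insulin pathway, leaned lower, while genes repressed by DAF-16 leaned higher. Of 75 genes of lipid metabolism, 11 were lower and 1 higher adjusted over the list alone, with 0 past the threshold in edgeR over all genes (2 higher and 19 lower at an unadjusted p under 0.05) and 9 lower in DESeq2. The stearoyl-CoA desaturases fat-7 and fat-6 had log2 fold changes of -2.16 ± 0.28 and -0.44 ± 0.06, and cpt-3, a carnitine palmitoyltransferase, of -1.08 ± 0.13 (SE). Of 22 genes induced by DAF-16, 6 were lower and 1 higher adjusted over the list alone, with 0 past the threshold in edgeR over all genes (1 higher and 9 lower at an unadjusted p under 0.05) and 3 lower and 1 higher in DESeq2. The catalase ctl-2 had a log2 fold change of -0.65 ± 0.07 and the ferritin ftn-1 of -0.71 ± 0.14, while the metallothionein mtl-2 was at 0.70 ± 0.10 (SE). The 12 genes repressed by DAF-16 had a median of 0.34, with 0 past the threshold in edgeR adjusted over the list alone, 0 by edgeR or DESeq2 over all genes, and 3 higher in edgeR at an unadjusted p under 0.05. The camera adjusted p was 0.012 for lipid metabolism (median -0.09), 0.025 for the induced list (median -0.16) and 0.0038 for the repressed list. Under an estimated correlation the adjusted p was 0.76 for each. The lipid call was lost without batch 4 or either of its libraries (adjusted p from 0.0501 to 0.0551); the induced list was lost without either batch 2 library (0.076 and 0.061) and the repressed list without the batch 2 pair or either library (0.10 to 0.12).

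Of 69 cytochrome P450 genes, which oxidise lipids and foreign compounds, 5 were lower and 1 higher adjusted over the list alone, with 0 past the threshold in edgeR over all genes (4 higher and 12 lower at an unadjusted p under 0.05) and 5 lower in DESeq2. The 4 with the smallest p were cyp-25A1 (log2 fold change -1.70 ± 0.14), cyp-37A1 (-0.97 ± 0.09), cyp-25A2 (-1.01 ± 0.12) and cyp-32B1 (-0.72 ± 0.10, SE). As a list they did not pass (median -0.07, camera adjusted p = 0.36), except without batch 2 (0.0091) or either of its libraries (0.020 and 0.021), with the stricter filter (0.0095) and in DESeq2 (0.015). Among other enzymes of detoxification, the 61 UDP-glucuronosyltransferases had a median of 0.12 (camera adjusted p = 0.0081) and the 43 glutathione S-transferases of 0.11 (0.0045). When the correlation was estimated, the adjusted p was 0.798 and 0.76. Adjusted over the list alone, ugt-47 passed and no glutathione S-transferase did (8 higher and 1 lower in edgeR at an unadjusted p under 0.05); DESeq2 called 2 higher in each list. The UDP-glucuronosyltransferase call ended without the batch 2 pair or either library (0.76 to 0.80) and without the batch block (0.082). The 15 SKN-1 targets did not pass (median 0.10, camera adjusted p = 0.21), except without the block (0.040).

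Intestinal products were higher in part. The 6 vitellogenins, yolk proteins made in the intestine, took 7.995 ± 1.34% of the counts with the empty vector and 10.3 ± 0.68% in the libraries labelled gtr-1 RNAi (SD, n = 3 each). The exact two-sided permutation p of that share was 0.25 over pairs and 0.1 over groups, the smallest values this design allows. vit-2 had a log2 fold change of 0.57 ± 0.14 and vit-1 of 0.33 ± 0.06 (SE), and these 2 passed when adjusted over the list alone; over all genes tested 0 passed in edgeR (3 higher at an unadjusted p under 0.05) and 3 were higher in DESeq2. Reads of the near-identical vitellogenins vit-3, vit-4 and vit-5 cannot be assigned with certainty. Of 14 intestine genes, 4 were higher adjusted over the list alone, among them asp-1 (0.58 ± 0.08) and the intestinal actin act-5 (0.25 ± 0.04, SE); 0 passed in edgeR over all genes (4 higher at an unadjusted p under 0.05) and 4 in DESeq2. The camera adjusted p was 0.0082 for the vitellogenins (median 0.23) and 0.00023 for the intestine genes (median 0.20). With an estimated correlation the adjusted p was 0.798 and 0.76. The vitellogenin call ended without the batch 2 pair or either library (0.57 to 0.61), where the median fell to 0.09. By batch pair the vitellogenin median was 0.52, -0.02 and 0.25 in batches 2, 3 and 4.

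Sperm genes and body wall muscle genes were called lower as lists with the preset correlation. The 55 sperm genes had a median log2 fold change of -0.59, which was 0.12 in batch 2, -0.67 in batch 3 and -1.4 in batch 4. None passed in edgeR adjusted over the list alone or over all genes (7 lower at an unadjusted p under 0.05), and DESeq2 called 1 lower; the major sperm protein genes msp-51 and msp-59 were at -0.92 ± 0.20 and -0.97 ± 0.28 (SE), and reads of these near-identical genes cannot be told apart with certainty. The 19 body wall muscle genes had a median of -0.21, which was -0.20 in batch 2, 0.015 in batch 3 and -0.45 in batch 4. In edgeR 0 passed adjusted over the list alone (5 lower at an unadjusted p under 0.05), and 2 were lower in DESeq2. mlc-2 was at -0.27 ± 0.08 and unc-87 at -0.31 ± 0.09 (SE). The camera adjusted p was 3.1e-06 for the sperm genes and 0.0055 for the muscle genes. The adjusted p with an estimated correlation was 0.822 for both. The muscle call ended without batch 4 or either of its libraries (0.20 each), where the median was -0.07. It also ended without either batch 2 library (0.051 and 0.061), where the median was -0.19. The 30 germline, oocyte and embryo genes did not pass (median -0.04, camera adjusted p = 0.067), except without batch 4 or either of its libraries (0.0078 to 0.0081) and in DESeq2 (0.015).

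The series' title names neuropeptide signalling and protein homeostasis, and camera left the lists grouped here under both mostly without a call. The lysosomal proteases and the vacuolar ATPase, which also bear on protein turnover, are described above and not counted here. camera with the preset correlation called both higher. fry's mixed test, which asks for change in either direction, passed the neuropeptide receptors (adjusted p = 0.021) and the chemoreceptor-family genes (0.0078). That test makes no reference to other genes, so these passes do not set either list apart from them. In edgeR at an unadjusted p under 0.05, 2 of 83 receptors were higher and 1 lower. Of 107 chemoreceptor-family genes 6 were higher and 6 lower, against 775 and 882 of all 15519 genes tested. The 30 FLP neuropeptide genes had a median log2 fold change of 0.04 (camera adjusted p = 0.12) and the 67 NLP genes of 0.04 (0.33); both were called higher without batch 4 or either of its libraries (0.00016 to 0.00020 and 0.0049 to 0.0059). The medians of 26 insulin-like peptides (-0.06, camera adjusted p = 0.58), 16 genes of neuropeptide processing (-0.01, 0.42), 83 neuropeptide receptors (0.00037, 0.51) and 36 G protein signalling genes (-0.02, 0.58) lay near 0. The 107 chemoreceptor-family genes had a median of -0.01 and a camera adjusted p of 0.21, and passed without the batch 4 empty vector library alone (0.038). The 30 synaptic genes had a median of -0.01 (camera adjusted p = 0.58) but were lower without the batch 3 pair or either of its libraries (0.010 to 0.014). For the chemoreceptor, neuropeptide processing, synaptic and mitochondrial unfolded protein response lists the median lay below 0 while the test leaned higher. camera compares a list with the other genes and not with 0. The median log2 fold change of all tested genes was -0.029, below the medians of these lists. The mean of the neuropeptide receptors lay below 0 while their median did not. No member of these 8 lists passed in edgeR adjusted over the list alone or over all genes; 13 were higher and 13 lower at an unadjusted p under 0.05, and DESeq2 called 3 higher and 1 lower.

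The 28 cytosolic heat shock chaperones had a median of 0.02 (camera adjusted p = 0.45), the 8 subunits of the chaperonin TRiC of -0.06 (0.28), the 10 genes of the mitochondrial unfolded protein response of -0.01 (0.63), the 27 autophagy genes of -0.03 (0.42) and the 23 ubiquitin and E2 genes of -0.05 (0.33). The 23 genes of the endoplasmic reticulum unfolded protein response had a median of -0.07 (camera adjusted p = 0.12), but passed in DESeq2 (0.0329) and without the batch 2 library labelled gtr-1 RNAi (0.0496). The 33 proteasome subunits were called lower by camera at a median of -0.07 (adjusted p = 0.0015), but with an estimated correlation the adjusted p was 0.822. The proteasome call ended without the block (0.064), without the batch 2 pair or either library (0.061 to 0.11) and without the batch 3 pair or either library (0.15 to 0.60). The 61 abu and pqn genes were called higher at a median of 0.11 (camera adjusted p = 0.0013; adjusted p = 0.822 with an estimated correlation). No member of these 8 lists passed in edgeR adjusted over the list alone; 6 were higher and 19 lower at an unadjusted p under 0.05, and DESeq2 called 2 higher and 0 lower. hsf-1, which encodes the main heat shock transcription factor, was at 0.01 ± 0.04, daf-16 at 0.07 ± 0.03, skn-1 at 0.01 ± 0.04 and the insulin receptor gene daf-2 at 0.03 ± 0.04 (log2 fold change, SE). The chaperone genes hsp-16.2 (0.11 ± 0.36), hsp-70 (-0.22 ± 0.25), hsp-4 (-0.13 ± 0.08) and hsp-6 (0.06 ± 0.07), and sod-3 (0.13 ± 0.18) and gst-4 (0.10 ± 0.22), did not pass either, with edgeR adjusted p from 0.514 to 0.969 over these 10 genes.

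Of the remaining lists, the 33 nuclear genes of the respiratory chain had a median of 0.06, with 6 higher and 0 lower adjusted over the list alone, 0 past the threshold in edgeR over all genes (8 higher and 1 lower at an unadjusted p under 0.05) and 1 higher in DESeq2. asb-2, a subunit of the ATP synthase, was at 0.27 ± 0.05 (log2 fold change, SE). The 78 cytosolic ribosomal protein genes had a median of -0.07, against -0.03 over all tested genes, and 75 of them lay below 0. None passed the threshold adjusted over the list alone or by edgeR or DESeq2 over all genes. In edgeR 1 was higher and 6 lower at an unadjusted p under 0.05. The camera adjusted p was 0.00023 for the respiratory chain (higher) and 0.00041 for the ribosomal proteins (lower). Under an estimated correlation the adjusted p was 0.822 for both. The ribosomal call ended without the batch 2 pair or either library (0.50 to 0.61). The 29 histones (median -0.22, camera adjusted p = 0.085) passed without the block (0.0047) and without batch 4 or either of its libraries (3.5e-08 to 1.9e-07). The 12 mitochondrially encoded genes (0.04, 0.36) passed without the batch 3 pair or either of its libraries (0.00040 to 0.00066). The 6 pharyngeal muscle genes (0.40, 0.21) passed without the batch 2 pair or either of its libraries (0.020 to 0.024). The 5 glial genes (0.11, 0.34) and the 35 genes of the small RNA and RNAi pathway (-0.02, 0.66) did not pass.

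**Figure D2:**
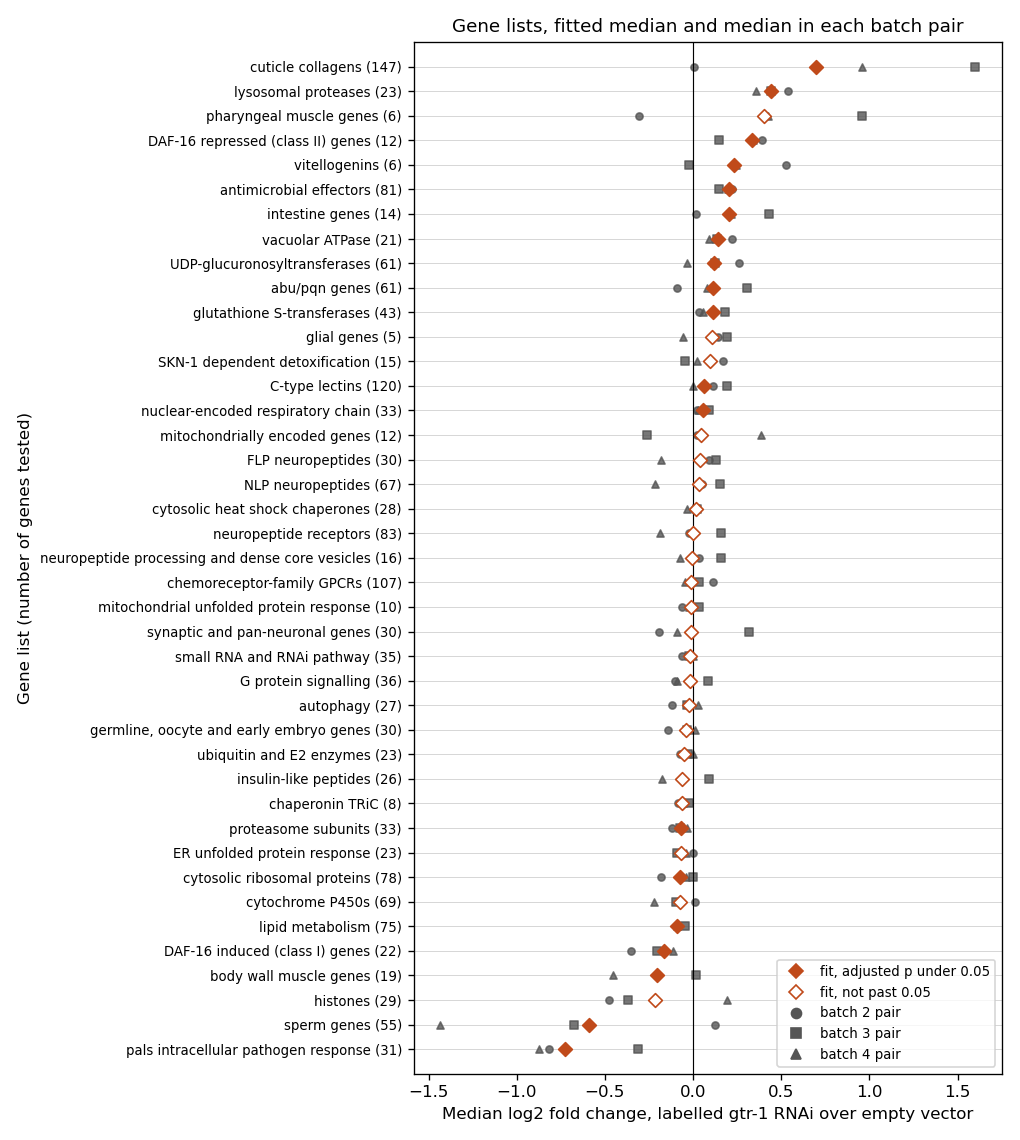
Median log2 fold change of the libraries labelled gtr-1 RNAi over the empty vector libraries for each of the 41 gene lists, with the number of genes tested in brackets. Diamonds are medians of fitted values, filled where the camera adjusted p with the preset correlation was under 0.05, and grey symbols are the medians in each batch pair. The cuticle collagens spread from 0.0049 in batch 2 to 1.6 in batch 3, while the lysosomal proteases lay between 0.36 and 0.54.

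In all, camera called 12 of the 41 lists higher and 7 lower with the preset correlation. With an estimated correlation 0 lists passed (smallest adjusted p = 0.76), 2 had an unadjusted p under 0.05, and fry, which asks whether a list's genes move on balance to one side, passed 0 lists (smallest adjusted p = 0.098) with 5 at an unadjusted p under 0.05. In fry's mixed test, which asks for change in either direction, 12 lists passed, among them the neuropeptide receptors and the chemoreceptor-family genes. Like fry's other test, it does not compare a list with other genes. The test with an estimated correlation rests on 2 residual degrees of freedom, so its lack of calls does not show that the lists are unchanged.

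The libraries of batch 2 stood apart from the others. The first principal component of the log2 CPM held 68.3% of the variance and set both batch 2 libraries (-77.8 and -69.9) apart from the other 4 (17.3 to 50.8). The second held 16.7% and set the empty vector libraries of batches 3 and 4 (-23.6 and -37.3) apart from those labelled gtr-1 RNAi (36.4 and 29.3), with -0.70 and -4.11 in batch 2. The log2 CPM of the batch 3 and batch 4 libraries correlated at r = 0.992 within either treatment and at 0.986 between the treatments within either batch; in batch 2 the treatments correlated at 0.989. The 10 most abundant genes took 10.7 ± 1.19% of the counts with the empty vector and 12.9 ± 0.64% in the libraries labelled gtr-1 RNAi (SD, n = 3 each; exact permutation p = 0.25 over pairs and 0.1 over groups, the smallest values possible, two-sided).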

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

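Robust quasi-likelihood and limma on the deposited batch-corrected values were chosen after seeing the data; the pseudocount, quantile and limma alternatives set for normalized values were not run, since the table holds counts, and gtr-1 had no value under the stricter filter, which removed it. The count of genes that rose (14) and fell (0) depended on the setting. Without the replicate block it was 1 higher and 0 lower. It was 123 and 42 with no filter on low counts, 6 and 0 with the stricter filter, 132 and 69 with DESeq2 size factors, 244 and 96 in DESeq2, 35 and 11 with robust quasi-likelihood, 79 and 35 at an adjusted p under 0.1, 10 and 0 with a fold change of 2 or more as well, and 585 and 362 with limma on the batch-corrected values. The limma fit counted 4 residual degrees of freedom where the batch correction leaves 2, so its error is understated. Leaving out a pair or a library gave 0 to 745 higher and 0 to 420 lower. All 14 genes kept their sign in the 15 refits by edgeR and DESeq2, which their rise in all 3 batch pairs made likely in advance. They stayed past the threshold with no filter, DESeq2 size factors, robust quasi-likelihood and DESeq2. With the stricter filter 6 did, and 1 without the block. The prior degrees of freedom, which set how much each gene borrows from the others, were 3.16 as reported, 2.83 without the block, 2.49 with the stricter filter, 5.20 with no filter and 6.38 with DESeq2 size factors, and the last 2 of these fits called the most genes; the cause was not tested further. Neither the lowest nor the highest of these counts is a firm number of differing genes.

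Of the lists, 12 higher and 7 lower became 0 and 0 with an estimated correlation, and 8 to 15 higher and 4 to 7 lower when a pair or library was left out; all 19 kept their direction in each alternative. The replicate block changed, of the list calls, those of the proteasome, UDP-glucuronosyltransferases, SKN-1 targets and histones. Over 83 genes followed by name, the alternatives other than leave-outs gave 364 values on the same side of the threshold, 110 newly past it, 21 no longer past it and 1 of the other sign. No gene past the threshold changed sign. For the values below, none of them past the threshold as reported, the sign of a gene or the direction of the test of a list changed somewhere, and the cause was not tested. skn-1 was at -0.0027 without the block. Left out by pair or library, log2 fold changes ran from -0.10 to 0.44 for rol-6, -0.0084 to 0.053 for hsf-1, -0.031 to 0.087 for skn-1, -0.0016 to 0.075 for daf-2, -0.42 to 0.50 for hsp-16.2, -0.58 to 0.091 for hsp-70, -0.026 to 0.12 for hsp-6, -0.20 to 0.32 for gst-4 and -0.23 to 0.50 for vit-4. List medians, where the test's direction changed, ran from -0.057 to 0.089 for NLP neuropeptides, -0.15 to -0.051 for insulin-like peptides, -0.085 to 0.088 for neuropeptide receptors (-0.026 with the stricter filter), -0.077 to 0.086 for chemoreceptor-family GPCRs, -0.13 to -0.00083 for G protein signalling, -0.15 to 0.16 for synaptic genes (-0.013 in DESeq2), -0.011 to 0.051 for heat shock chaperones, -0.062 to 0.016 for the endoplasmic reticulum response, -0.028 to 0.037 for the mitochondrial response, -0.067 to 0.017 for autophagy, -0.11 to 0.26 for mitochondrially encoded genes and -0.039 to 0.028 for the RNAi pathway (0.013 with the stricter filter). gtr-1 stayed above 0, with adjusted p from 0.90 to 1.00. Depth limits genes near the count minimum, of which gtr-1 is an example.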

Other observations

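The tests of whether gtr-1 had too few reads and of exchanged labels were chosen only after the result was seen. The hypotheses on heme, vitamin B12, collagens and the batch-corrected values came from patterns in these data, and their tests were written before the results those tests measure.

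Gene families taken by name were also tested, and some of them lie within the lists. Over 138 families, camera with the preset correlation called 18 higher and 8 lower, and with an estimated correlation 0 passed (smallest adjusted p = 0.991, 3 at an unadjusted p under 0.05). Higher families included the F-box genes fbxb (101 tested, median log2 fold change 0.18), the cuticlin-like genes cutl (26, 0.21), the transthyretin-related genes ttr (49, 0.09) and abu (10, 0.83), which is part of the list of abu and pqn genes; cutl had 2 members and ttr 3 higher adjusted over the list alone, while fbxb and abu had 0 by edgeR and 0 by DESeq2. Lower families included both sets of mitochondrial ribosomal proteins, mrpl (42, -0.10) and mrps (29, -0.11), with 0 members past the threshold by edgeR adjusted over the list alone and 0 by DESeq2. The adjusted p of all 6 families was 0.991 with an estimated correlation.

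Heme handling was the first hypothesis tested. The rise of hrg-2 and hrg-7 may reflect a lower supply of heme, which C. elegans takes from its bacteria, and then other heme-responsive genes ought to be higher too. Their median log2 fold change over hrg-1, hrg-3, hrg-4 and mrp-5 was 0.53 (SE 0.24), just over the 0.5 set in advance; all 4 lay above 0, with edgeR adjusted p from 0.0079 to 0.039 adjusted over the list alone and from 0.15 to 0.44 over all genes. This is consistent with the hypothesis, although the margin over 0.5 is smaller than the SE. For cth-1 and R08E5.3 a lower supply of vitamin B12 was tested through 5 genes of the propionate shunt, which is induced when B12 is low. Their median was 0.23 (SE 0.19), between the 0.2 and 0.5 set in advance, so the test left the hypothesis open.

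The cuticle collagens were higher by their median in batches 3 and 4 and not in batch 2. Across the 147 collagens the log2 fold change followed the difference of batch 2 from batches 3 and 4 (r = 0.749, Spearman 0.79, against r = 0.010 over all tested genes; genes are not independent replicates), and collagens were higher in batch 2 by a median of 2.83 on the log2 scale. A difference of the kind that sets batch 2 apart is therefore a candidate explanation for the collagens. Over all tested genes the treatment difference did not follow that batch difference, as the r of 0.010 shows. The sperm gene msp-59 went the other way. It had 967 and 728 counts in batch 2 and 45 to 139 elsewhere, but was lower in the libraries labelled gtr-1 RNAi. The list of sperm genes was not set against the batch difference. Whether that difference is one of culture age or stage was not tested. The labels give all libraries the same day of adulthood and the same temperature. More larval progeny in the libraries labelled gtr-1 RNAi could also raise collagens. The 20 larval moulting genes had a median of 0.32 (SE 0.086), between a bound of 0.174 and the 0.348 this hypothesis needs. The hypothesis of more progeny therefore stays open. An effect of the treatment, which the labels name, is also open and was not told apart from either.

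gtr-1 was not lower in the libraries labelled gtr-1 RNAi. Too few reads to see a fall by a factor of 2 would need a 95% interval that reaches a log2 fold change of -1, and its lower end was -0.64, so low depth alone does not account for a missed fall by that factor. A smaller fall, down to 0.643-fold at that end, stays within the interval. Labels exchanged within pairs were tried in all 7 ways. In 6 of them, that of all 3 pairs included, the lower end lay from -0.89 to -0.50, so these exchanges do not hide a fall by a factor of 2 either. An exchange in batches 2 and 3 together is not excluded by gtr-1 itself: there its log2 fold change is -0.26 ± 0.29 (SE) and the interval reaches -1.03. Other genes argue against that exchange, which called 0 genes, against 14 with the labels as given. It would also set batch 3 against batch 4 on the second principal component. There the empty vector libraries lay at -23.6 and -37.3 and those labelled gtr-1 RNAi at 36.4 and 29.3. Taken as they stand, with an interval from -0.64 to 0.89, the values also allow that gtr-1 RNA did not fall at all. In that case the 14 genes would not reflect a loss of gtr-1 RNA. A library from outside these pairs, reads from the double-stranded RNA itself and an effect confined to a few neurons or to protein remain possible explanations too. None of these was tested.

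The deposited batch-corrected values show smaller differences between treatments than the normalized counts they come from. Of 1287 genes with a log2 ratio of 0.5 or more in either direction, 1287 lay nearer to 0 after the correction, with a median ratio of 0.741; among the 14 genes that rose it was 0.744. ComBat (sva 3.50.0) on the normalized values without a treatment term gave the deposited values to a median relative difference of 1.07e-15. ComBat with a treatment term (0.0158) and subtraction of batch means by limma (0.0217) did not; both lie under the bound of 0.1 set in advance, which was too wide, and they are excluded because the first procedure matches to rounding error.

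The 6 libraries can be split into equal groups in 10 ways, too few for a share under 0.05, so this cannot show whether chance is excluded. The real split gave 14 genes, 1 of the 10 splits gave as many, itself included, and the highest of the others gave 2. The real split parts all 3 batch pairs, as do 4 splits in all, and the highest other among these also gave 2.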
